A study of Mus musculus with 12 samples.

How the data were processed

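The data are 4sU-seq counts per gene from 12 libraries of ZFP207-degron mouse embryonic stem cells, in 6 rescue groups of 2 libraries, all treated with IAA for 5 h. The deposited table holds raw counts for 55401 genes in 12 columns, with each gene given as a versioned Ensembl identifier and a symbol. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1, DESeq2 1.42.0 and the mm10 genome were used, with no order, parameters or filters stated. The values were whole numbers whose column totals differed, as counts do. Groups were taken from the sample labels, which number the replicates but do not say whether they are separate cultures.

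Each column was checked against the gene names by its correlation, over genes, with the other columns on the log2 scale. Among 11 columns r was 0.961 to 0.98, and ZF1,2-H2A replicate 2 gave at most 0.035, with 0 counts at 6733 of 11225 genes whose median count exceeded 100. That column was left out and not realigned, a choice made after the data were examined. ZF1,2-H2A therefore had 1 library, assumed to vary like the other groups. The alternative with all 12 columns was also run.

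Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 21364, and libraries were scaled with TMM factors. A quasi-likelihood model with group means was fitted to 11 libraries (5 residual degrees of freedom, biological coefficient of variation 0.198), and 12 comparisons were tested with a 2-sided quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Some counts at an unadjusted p under 0.05 are given too. With no true change a share of about 0.05 of the genes tested, or of a list's members, would have such a p if the fit held the right spread. Without the replicate block described below, the difference between replicate numbers stays in the spread. That share can then be smaller where the sides compared hold the same numbers. CPM values are TMM-scaled, and their SD is over the 2 libraries of a group. A gene at 0 in a group was given a lower bound on its fold, against a floor of 3 counts in a library, which covers counting error only. Total counts per library ran from 7774113 to 30890181, so that 3 counts correspond to 0.39 CPM in the shallowest library and 0.097 CPM in the deepest. The spread between replicates was 13.3 to 34.2 times what counting alone gives (chi-squared per degree of freedom, over all genes of a group together).

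Whether the replicate numbers pair samples across groups was checked by correlating the difference between the 2 replicates of one group with that of another, across genes, which are not independent replicates. Over 9589 genes with a mean CPM of 10 or more, a level chosen after the data were examined, r was 0.50 to 0.63 in 10 pairs of groups, and over all tested genes it was 0.07 to 0.14. The first principal component (32.0% of the variance) separated the replicate numbers. A fit with the number as a block (4 residual degrees of freedom, coefficient of variation 0.12) is therefore given beside the count of each comparison, and its calls beside the list members called against FL. The labels do not say what the number stands for.

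Before the data were examined, 27 gene lists, the comparisons, the tests, the first set of alternatives and the rule for named genes were fixed. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), with adjustment over the lists of a comparison, and their members were also adjusted over the list alone. After the data were examined, a symbol on several lines of the table was kept as the line with the highest mean CPM in the lists. Named genes were Zfp207 and Fus, and genes with an absolute log2 fold change of at least 1, a mean CPM of at least 2, both libraries of one group above both of the other, and a symbol other than a Gm number, a Rik clone or an accession. Of these the 10 largest rises and falls were taken for EV against FL and 4 for every other comparison. Up to 4 called members of each list, or its member of smallest p, were added, and in other comparisons the called members among the 2 smallest p of a list. Gene spans and coordinates came from a RefSeq table of GRCm38.p6, the assembly of mm10, matched by symbol for 17897 of 21364 tested genes (83.8%). A class of single-exon genes could not be formed, since the table gives no exon numbers.

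Shared calls were set beside the number expected from independent draws and beside 20 simulated unchanged groups against the same FL libraries. Another 20 draws held the fitted replicate effect and the dispersions of the blocked fit, a choice made after the data were examined. The calls were counted again with EV and the construct against different FL libraries. The position of each library was its projection on the EV minus FL direction of log2 CPM (prior count 2), with the direction from FL and EV libraries of one number and the measurement from those of the other, averaged over both ways.

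Gene calls for 3 comparisons with FL, a list and a position were tested on simulated data, while the span classes, the check of pairing, the split of FL libraries and DESeq2 were not. Draws fitted without the block held the dispersions of the unblocked fit and no replicate effect, unlike the paired libraries. Draws fitted with it held the dispersions of the blocked fit and the fitted replicate effect. Shares without and with the block thus come from unlike data and do not measure what the block gains. For EV against FL, over 21364 genes with 100 planted changes of each size, 55.0% of 2-fold and 93.0% of 4-fold changes were called (78.0% and 97.0% with the block). Among all calls 10 of 158 were genes with no planted change, and 23 of 198 with the block, more than the 5% aimed at, so counts with the block may hold more false calls than the threshold states. For N-IDR1 against FL the shares were 43.0% and 93.0%, with 9 of 145 calls unplanted and 25 of 198 with the block. For ZF1,2-H2A against FL with 1 library they were 20.0% and 86.0%, with 10 of 116 and 12 of 159 unplanted. A list planted at a log2 fold change of 0.5 in EV against FL was recovered at an adjusted p of 2.3e-25 (0.0037 with an estimated correlation) with 0 of the other lists called. A planted position of 0.5 was recovered as 0.47 to 0.60.

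The alternatives were DESeq2 1.42.0, RLE factors, library totals, no filter on low counts, a CPM above 1 in 2 libraries, the replicate block, only the 2 groups compared, and each library left out in turn. Others were chosen after the data were examined: all 12 columns, N-IDR1 1 left out with and without the block, N-IDR1 2 left out with the block, DESeq2 with the block, lists with the block and an estimated correlation, shared calls with split FL libraries, and positions over genes of a mean CPM of 10 or more or against FL and EV of the same number. Tables were checked and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.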

Results

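Newly made RNA was measured in mouse embryonic stem cells of the 129/Ola strain whose zinc finger protein ZFP207 can be degraded through an auxin-inducible degron. Transcripts made in a short window were labelled with 4-thiouridine (4sU), biotinylated, enriched on streptavidin and sequenced. All cells received auxin (IAA) for 5 h and carried 1 of 6 rescue constructs, with 2 libraries per group. These were full-length ZFP207 (FL), an empty vector (EV) and the ZFP207 mutants N-IDR1, N78-FUS-IDR, N78 and ZF1,2-H2A, named here as in the labels. The stated purpose was to learn how well truncated or altered ZFP207 restores the immediate function of the protein, which the study connects with U1 snRNP, spliceosome assembly and phase separation. The values are counts per gene, which carry no information on splicing itself. Total counts of replicates 1 and 2 were 30890181 and 20576963 in FL, 29411937 and 18269192 in EV, and 7774113 and 15201765 in N-IDR1. They were 16520336 and 17609963 in N78-FUS-IDR, 22923521 and 19980854 in N78, and 11329211 in replicate 1 of ZF1,2-H2A. The column of ZF1,2-H2A replicate 2 did not follow the gene names (r = 0.035 at most with any other column, against 0.961 to 0.98 among the other 11) and was not used, so ZF1,2-H2A rests on 1 library. Of 55401 genes listed, 21364 were tested. No spike-in is described, so every change is relative to the rest of the library.

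Zfp207 itself, on chromosome 11 (80383279 to 80408561, GRCm38), gave 1390 ± 86 CPM with FL. CPM are counts scaled to a common library size, given as mean ± SD with n = 2 per group unless stated. It gave 681 ± 8 with EV, a log2 fold change of -1.03 (adjusted p = 0.0018). With N-IDR1 it stood at 1340 ± 47 and in the 1 library of ZF1,2-H2A at 1450 CPM, 0.98 and 1.09 above EV on the log2 scale (adjusted p = 0.022 and 0.017). N78-FUS-IDR and N78 gave 795 ± 76 and 911 ± 60 CPM, both lower than FL (log2 fold change -0.81 and -0.61, adjusted p = 0.024 and 0.022). These counts add transcripts of the endogenous gene and of whatever part of the construct maps to it. They do not give the amount of construct protein. A low level of a construct was thus not told apart from a weak function, in any comparison below. Fus, an RNA-binding protein gene on chromosome 7 (127966789 to 127982032), gave 1140 ± 21 CPM in N78-FUS-IDR and 770 ± 72 in FL. That log2 difference of 0.57 had an adjusted p of 0.14, and of 0.00046 with the replicate number as a block. The labels do not say whether the FUS part of the construct was taken from this mouse gene.

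**Figure D1:**
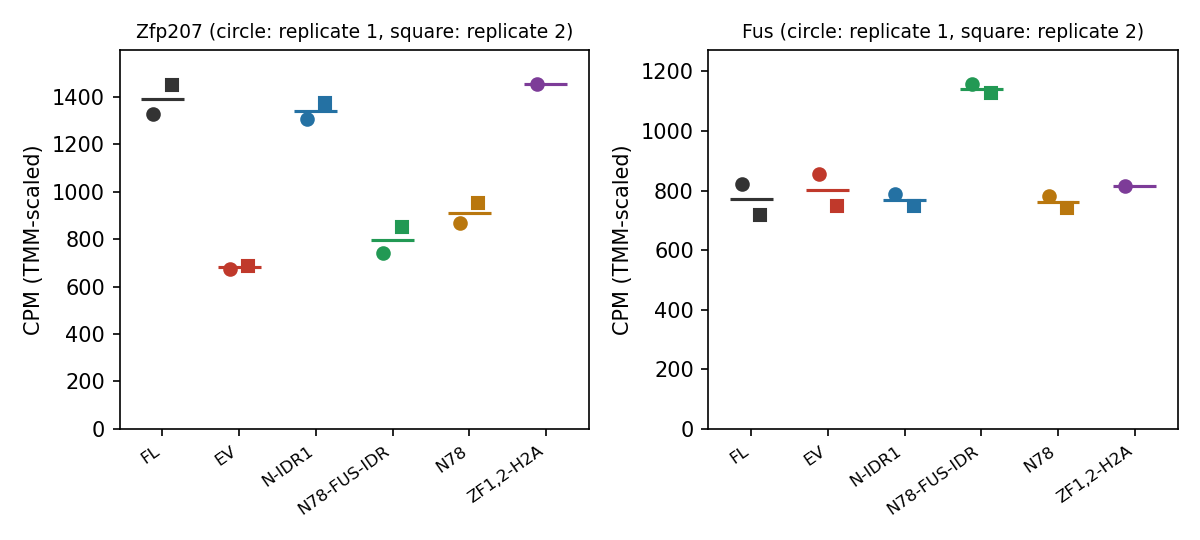
CPM (TMM-scaled counts, linear axis from 0) of Zfp207 and Fus in each of the 11 libraries, with circles for replicate 1, squares for replicate 2 and lines for group means. Zfp207 lay between 675 and 954 CPM in EV, N78-FUS-IDR and N78 libraries and at 1307 CPM or more in the others, and Fus was highest in both N78-FUS-IDR libraries (1156 and 1126 CPM).

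The comparison of EV with FL asked what newly made RNA loses or gains without ZFP207, relative to full-length rescue. No group was left without IAA as a reference for the natural level. Among the named genes, Hspbap1 (chromosome 16, 35769726 to 35828462) fell from 182 ± 3 to 27.1 ± 1.4 CPM, a log2 fold change of -2.74 (adjusted p = 4e-04). Xpnpep3, a mitochondrial aminopeptidase, fell from 43.4 ± 1.9 to 5.19 ± 1.2 CPM (-3.08, adjusted p = 0.00052). Mettl8, a methyltransferase of mitochondrial transfer RNA, fell by 3.0 and Dzip3, a ubiquitin ligase gene, by 2.68 on the log2 scale. Further large falls were those of Hnf4a, a nuclear receptor of liver and endoderm (-3.39, at 0.558 ± 0.28 CPM in EV), Ccdc51 (-3.17), Lrguk (-2.79), Epdr1 (-2.77), Rslcan18 (-2.66) and Wdr86 (-2.60). Inka2, an inhibitor of the kinase PAK4, rose by 1.10, Hpcal1 by 1.08 and Igdcc4 by 1.00 on the log2 scale.

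Genes of DNA repair were among those that fell. Of the 26 tested members of that list, 6 fell and 0 rose (edgeR, all genes), and 7 fell when adjusted over the list alone. With the replicate number as a block, described with the totals, 10 fell and 1 rose. Fancd2, a core protein of interstrand crosslink repair (chromosome 6, 113531640 to 113597020), fell from 87.6 ± 2.6 to 22.1 ± 2 CPM (log2 fold change -1.99, adjusted p = 4e-04). Rad50, part of the complex that senses broken DNA ends, fell by 1.56, Fanca by 1.02 and Palb2, the partner of BRCA2, by 0.87 on the log2 scale. Atr and Fanci were the other 2. The list as a whole was lower with the preset correlation (adjusted p = 1.1e-07) but not with an estimated one (adjusted p = 0.37 with an estimated correlation).

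Targets of p53 gave 2 rises and 1 fall among 32 tested members, and 13 rises and 3 falls when adjusted over the list alone, and 16 and 3 with the block. Plk2, a polo-like kinase, rose from 129 ± 4 to 251 ± 4.4 CPM (0.95, adjusted p = 0.004), Btg2, an antiproliferative gene, rose by 0.68, and Sulf2, a heparan sulfate sulfatase, fell by 0.94 on the log2 scale. The list's adjusted p was 8.7e-07, and its adjusted p was 0.09 with an estimated correlation. Host genes of small nucleolar RNAs (snoRNA) gave 2 rises among 26, Gas5 (0.47) and Snhg5 (0.60), and 7 when adjusted over the list alone, with 9 rises and 1 fall with the block (adjusted p = 7.3e-06 for the list, adjusted p = 0.15 with an estimated correlation). Among factors of 3' end processing and termination, Pcf11 (-0.73) and the Integrator subunit gene Ints3 (-0.68) fell, 2 of 27, both also adjusted over the list alone, and 4 rose and 4 fell with the block. Among SR proteins and their kinases, Srpk2 fell (-0.81), 1 of 27, although the list lay on the higher side (median log2 fold change 0.22, adjusted p = 0.0026, adjusted p = 0.37 with an estimated correlation). With the block 8 of these rose (Clk4, Son, Srsf1, Srsf2, Srsf3, Srsf5, Srsf6 and Srsf10, named after their values were seen) and Srpk2 fell. Of the neural genes, Map2 fell (-1.33) and Neurod1 rose (0.98), the same 2 as with the block. Of the 35 pluripotency genes 0 passed by edgeR, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 by DESeq2 (median 0.05). With the replicate block Tbx3 rose and Tdh fell. Of 14 genes of fibroblasts and feeder cells 0 passed either way, with 3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 with the block.

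The lists of spliceosome parts lie closest to the study's question. Of the 26 genes of U1 snRNP and its partners 0 passed by edgeR over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 (median 0.14, list adjusted p = 0.035, adjusted p = 0.44 with an estimated correlation). With the block Snrpa rose and Tia1 fell. Of the 45 genes of U2 and the tri-snRNP 0 passed either way, with 5 at an unadjusted p under 0.05 and 2 by DESeq2 (median 0.08, list adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation). With the block Cdc5l, Phf5a, Sf3b3, Rbm17 and Aqr rose and U2surp fell, all of these block calls named after their values were seen. Genes of the integrated stress response, which ATF4 drives, gave 0 calls of 28 over all genes (9 at an unadjusted p under 0.05, 4 by DESeq2) and 5 falls adjusted over the list alone, and 9 fell with the block. The median of these stress genes was -0.18 (list adjusted p = 0.0026, adjusted p = 0.39 with an estimated correlation). In all 16 of 27 lists passed with the preset correlation, 14 higher and 2 lower (DNA repair and integrated stress), and 0 with an estimated one.

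In total 459 genes changed in EV, 35 higher and 424 lower, with a median absolute log2 fold change of 1.10. The replicate numbers paired the samples, and with the number as a block 1910 genes passed (676 higher, 1234 lower), among them all 459. Single libraries were left out below without the block unless stated. For groups with both numbers this also left the sides compared unequal in replicate number. The count was 54 without FL 1, 81 without FL 2, 176 without EV 1 and 120 without EV 2. Of 28 named genes past the threshold, 11 passed under every such omission of a library of these groups: Zfp207, Hspbap1, Xpnpep3, Ccdc51, Mettl8, Lrguk, Epdr1, Dzip3, Rad50, Fancd2 and Plk2.

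**Figure D2:**
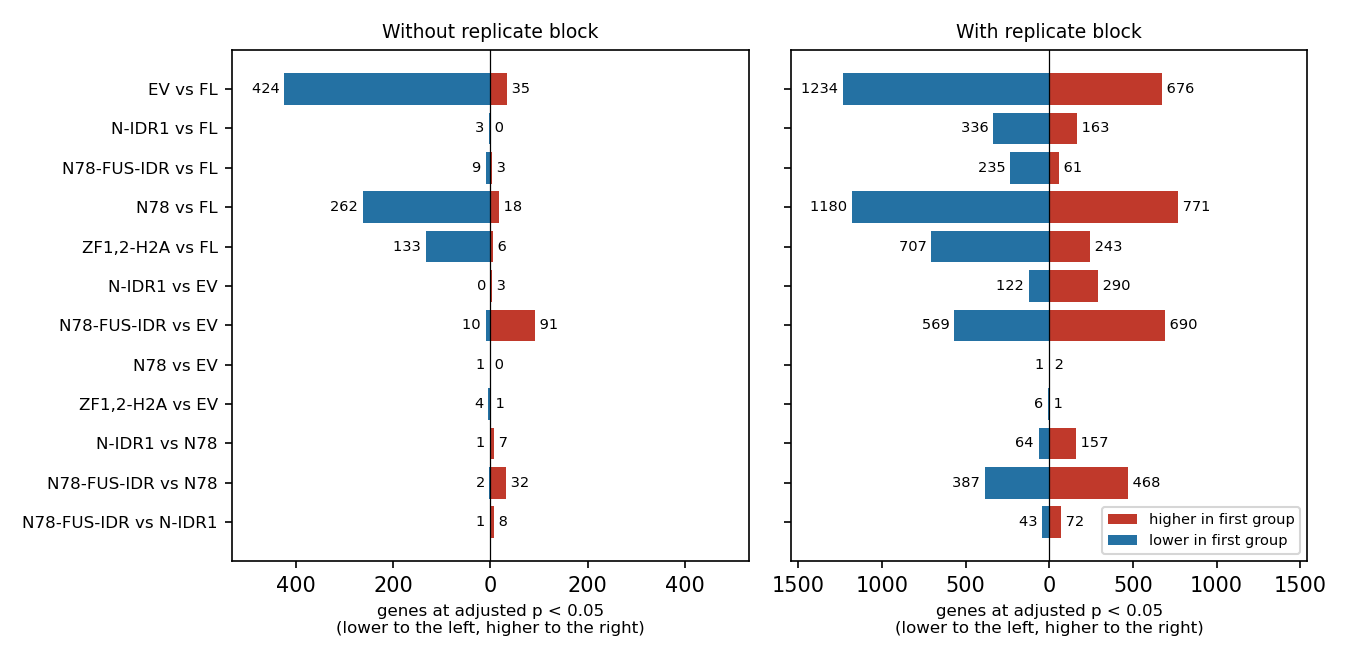
Number of genes past an adjusted p of 0.05 in each of the 12 comparisons (bars to the left, lower in the first group; bars to the right, higher), without and with the replicate number as a block. Without the block 424 genes were lower and 35 higher in EV than in FL, while N78 and EV differed by 1 gene.

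N-IDR1 was compared with FL to see what this mutant leaves unrestored. Hspbap1 fell to 49.2 ± 9.8 CPM from 182 ± 3 (log2 fold change -1.89, adjusted p = 0.013). Olfr984, an olfactory receptor gene, fell to 0.959 ± 0.056 from 6.94 ± 1.6 CPM (-2.84, adjusted p = 0.046). Its mean in EV was 2.6 ± 0.3 CPM, above that in N-IDR1, so this fall is not just a lack of rescue. The difference between N-IDR1 and EV was not called for this gene. The third gene, 1110002L01Rik, chosen after its values were seen, fell by 1.46 on the log2 scale. DNA repair gave 0 calls of 26 over all genes (edgeR; 8 at an unadjusted p under 0.05, 4 by DESeq2) and 6 falls adjusted over the list alone (list adjusted p = 0.00017, adjusted p = 0.46 with an estimated correlation), with Fancd2 at 45.9 ± 1.6 and Rad50 at 35.5 ± 2.1 CPM. With the block 8 of the repair genes fell, Fancd2 and Rad50 included. Pluripotency genes had 0 calls of 35 over all genes (8 at an unadjusted p under 0.05, 1 by DESeq2) and 2 rises adjusted over the list alone, and 5 rose with the block (median 0.13, list adjusted p = 0.00012, adjusted p = 0.11 with an estimated correlation). The smallest list p was that of histone genes (median 0.25, list adjusted p = 1.4e-08, adjusted p = 0.46 with an estimated correlation). Of these 0 of 63 passed over all genes or over the list alone by edgeR (4 at an unadjusted p under 0.05, 0 by DESeq2), and 5 rose with the block. Genes of mitosis and the kinetochore came next (median 0.15, list adjusted p = 2.5e-05, adjusted p = 0.11 with an estimated correlation).

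The count of 3 (0 higher, 3 lower, edgeR) stood beside 1969 genes at an unadjusted p under 0.05 and 121 genes by DESeq2. Unadjusted counts, here and elsewhere, are to be read against about 0.05 of 21364 genes with no true change. Without the block that share can be smaller where the sides compared hold the same replicate numbers. With the block 499 genes passed (163 higher, 336 lower), and 83 did with the block and without the shallow N-IDR1 1 and 202 with the block and without N-IDR1 2, each leaving 1 library in the group. Without the block it was 2 without FL 1 (both higher, so that none of the 3 falls passed), 0 without FL 2 (1226 at an unadjusted p under 0.05), 3 without N-IDR1 1 and 14 without N-IDR1 2. Of the 2 named genes neither passed under each of these omissions.

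N78-FUS-IDR was compared with FL to see what remains different when, as its label reads, the disordered region of FUS is joined to N78. Genes of the 2-cell-like state, which a small fraction of embryonic stem cells enters, were higher as a group. Zscan4c rose from 30.7 ± 2.8 to 68.6 ± 3.9 CPM (log2 fold change 1.16, adjusted p = 0.032) and Zscan4e from 22.4 ± 1.2 to 54.0 ± 2.2 CPM (1.27, adjusted p = 0.024). These 2 of 28 members rose over all genes, 14 rose adjusted over the list alone, 10 rose with the block and 0 fell, and the list's median was 0.96. Its adjusted p was 1.6e-30, and its adjusted p was 0.011 with an estimated correlation, the only list call of the 5 comparisons with FL that held there. Members of the Zscan4 and Usp17l families are near copies, so counts of single members are uncertain.

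Among the falls, Hspbap1 reached 33.1 ± 6.8 CPM (-2.46, adjusted p = 0.0012), Olfr984 fell by 3.53 and D3Ertd751e by 2.13 on the log2 scale. Olfr984 stood at 0.596 ± 0.084 CPM here, below its 2.6 ± 0.3 CPM in EV. Fancd2 fell to 30 ± 3.2 CPM (-1.55), 1 of 26 repair genes, with 5 adjusted over the list alone and 7 with the block (list adjusted p = 3.9e-07, adjusted p = 0.55 with an estimated correlation). Zfp207 is given above, and Tnrc6b (-0.89), a protein of microRNA silencing, Iars2 (-1.14), the mitochondrial isoleucyl-tRNA synthetase, 1110002L01Rik (-1.53), AC240460.1 (-2.80) and the riser Gm10167 (1.78) were chosen after their values were seen. In all 12 genes changed, 3 higher and 9 lower. With the block 296 passed (61 higher, 235 lower). The count was 5 without FL 1, 2 without FL 2, 4 without N78-FUS-IDR 1 and 1 without N78-FUS-IDR 2, and of 7 named genes Hspbap1 alone passed under each of these omissions.

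N78 was compared with FL to see what that part alone restores. Hspbap1 fell to 25.8 ± 0.35 CPM (log2 fold change -2.82, adjusted p = 0.00018), Epdr1 by 2.84 and Wdr86 by 2.82 on the log2 scale. Cttnbp2nl (chromosome 3, 105001915 to 105053146), a relative of the cortactin-binding protein gene Cttnbp2, fell to 9.65 ± 2.2 from 70.5 ± 7.7 CPM (-2.86, adjusted p = 0.00018). Its group means were 46.4 to 69.8 CPM in the 4 other groups. Scamp4 (1.33), Ubxn10 (1.28) and Rtkn (1.09), a Rho-binding protein gene, rose.

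In the DNA repair list 6 of 26 fell, 7 adjusted over the list alone and 11 with the block (where 1 rose), including Fancd2 (-1.82), Rad50 (-1.52), Palb2 (-0.97) and Fanca (-0.86). The list's adjusted p was 2e-10, and its adjusted p was 0.26 with an estimated correlation. Of the p53 targets Plk2 (0.84), Ddit4 (0.82), an inhibitor of mTORC1, and Btg2 (0.60) rose, 3 of 32 with 0 falls, 9 rose and 2 fell adjusted over the list alone, and 17 rose and 3 fell with the block (list adjusted p = 9.9e-07, adjusted p = 0.11 with an estimated correlation). The snoRNA hosts Snhg3 (0.63) and Snhg12 (0.56) rose, 2 of 26, with 6 adjusted over the list alone and 14 rises and 2 falls with the block (list adjusted p = 7.4e-06, adjusted p = 0.12 with an estimated correlation). Hspa8, a constitutive chaperone, rose by 0.43 on the log2 scale, 1 of 18 heat shock genes, of which 4 rose and 1 fell with the block. Of the 79 ribosomal protein genes 0 passed over all genes by edgeR and 0 adjusted over the list alone, with 33 at an unadjusted p under 0.05 and 5 by DESeq2. All had positive values (median 0.32, list adjusted p = 6.7e-19, adjusted p = 0.26 with an estimated correlation), and 34 rose with the block.

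Of 280 genes that changed, 18 were higher and 262 lower in N78. With the block 1951 passed (771 higher, 1180 lower). The count was 21 without FL 1, 30 without FL 2, 16 without N78 1 and 8 without N78 2, and Epdr1, Hspbap1, Cttnbp2nl and Fancd2 were the 4 of 19 named genes that passed under each of these omissions.

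ZF1,2-H2A was compared with FL on its 1 library, whose spread was assumed to equal that of the other groups. Srd5a1, a steroid 5-alpha reductase gene, Ggt1, gamma-glutamyltransferase, Cyb5rl and Acad10 had 0 counts there. Against a floor of 3 counts in that library they were at least 14.8-fold, 18-fold, 19.6-fold and 17.7-fold lower than in FL. These bounds cover counting error only, not the spread between libraries. Inka2 rose by 1.07, and Pagr1a by 3.45 on the log2 scale, from 0.765 ± 0.3 to 8.24 CPM. Pagr1a was uneven elsewhere too, with 10.7 ± 7.5 CPM in N-IDR1. Of all genes named for this comparison, only Srd5a1 and Fancd2 stayed past the threshold whichever FL library was left out. DNA repair gave 4 falls of 26, Fancd2 (-1.93), Rad50 (-1.33), Palb2 (-1.14) and Fanca (-1.01), with 6 adjusted over the list alone and 9 with the block (list adjusted p = 9.8e-05, adjusted p = 0.50 with an estimated correlation). Of the p53 targets Plk2 rose (0.94), 1 of 32, with 7 rises and 1 fall adjusted over the list alone and 10 and 1 with the block (list adjusted p = 2.3e-07, adjusted p = 0.073 with an estimated correlation). In total 139 genes changed, 6 higher and 133 lower, and 25 of the lower ones were at 0 counts in the ZF1,2-H2A library. With the block 950 passed (243 higher, 707 lower), and the count was 22 without FL 1 and 14 without FL 2.

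The 424 genes that fell in EV were followed in each construct. Their median log2 fold change against FL was -1.17 in EV, -0.99 in N78, -1.08 in ZF1,2-H2A, -0.53 in N-IDR1 and -0.42 in N78-FUS-IDR. Against EV the medians were 0.71 in N78-FUS-IDR, 0.64 in N-IDR1, 0.17 in N78 and 0.07 in ZF1,2-H2A. Since these genes were chosen for high values in the 2 FL libraries and low ones in EV, selection adds to each difference, from FL and from EV. Of the genes that fell in N78, 229 of 262 also fell in EV, where 5.2 would be shared by independent draws. The numbers were 102 of 133 for ZF1,2-H2A (2.6 by independent draws), 9 of 9 for N78-FUS-IDR (0.18) and 3 of 3 for N-IDR1 (0.06). Zfp207 itself, whose counts may include construct transcripts, is among the falls that N78 and N78-FUS-IDR shared with EV. All comparisons used the same 2 FL libraries. In 20 simulated unchanged groups set against the same FL libraries at most 1 shared fall arose, and the covariance of the log2 fold changes exceeded the simulated one by 0.318 for N78, 0.441 for ZF1,2-H2A, 0.247 for N-IDR1 and 0.163 for N78-FUS-IDR. Their correlation was above the simulated one for N78 (0.566 against 0.487) and ZF1,2-H2A (0.393 against 0.326) and below it for N-IDR1 (0.404 against 0.445) and N78-FUS-IDR (0.435 against 0.478). A simulated group with no true change can hold few calls, here and in the draws below. Its shared falls were thus bound to be few, and are no measure for groups with many true changes. These first draws ignored the pairing by replicate number. In 20 others, added after the data were seen and drawn with the replicate effect and fitted with the block, at most 3 falls were shared. The blocked covariance exceeded theirs by 0.385 for N78, 0.502 for ZF1,2-H2A, 0.318 for N-IDR1 and 0.224 for N78-FUS-IDR, and the correlation was again above them for N78 (0.574 against 0.489) and ZF1,2-H2A (0.395 against 0.311) and below for N-IDR1 (0.417 against 0.437) and N78-FUS-IDR (0.444 against 0.473).

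The controls were also split, an alternative added after the data were seen, with EV set against 1 FL library and the construct against the other. With EV against FL 1, 18 of 20 falls in N78 were shared with EV (0.11 by independent draws), 14 of 22 in ZF1,2-H2A (0.12), 2 of 3 in N78-FUS-IDR (0.017) and 0 of 0 in N-IDR1 (edgeR, 328 shared at an unadjusted p under 0.05, DESeq2 not run). With EV against FL 2 they were 24 of 34, 9 of 14, 1 of 2 and 0 of 0 (edgeR, 339 shared at an unadjusted p under 0.05). With the block as well, 330 and 303 falls were shared for N78, 183 and 270 for ZF1,2-H2A, 33 and 39 for N78-FUS-IDR and 37 and 27 for N-IDR1, where independent draws give 14 at most. Without the block the covariance was 0.340 and 0.306 for N78, 0.350 and 0.309 for ZF1,2-H2A, 0.204 and 0.195 for N-IDR1 and 0.189 and 0.146 for N78-FUS-IDR, against 0.639, 0.763, 0.567 and 0.485 with shared controls. With the block it was 0.234 and 0.217 for N78, 0.155 and 0.364 for ZF1,2-H2A, 0.163 and 0.081 for N-IDR1 and 0.084 and 0.046 for N78-FUS-IDR. The correlation was 0.09 to 0.213 without the block and 0.026 to 0.137 with it, lower than with shared controls in each case. At the 121 genes that fell in EV against FL 1, the medians against FL 2 were -1.26 in N78, -1.40 in ZF1,2-H2A, -0.57 in N-IDR1 and -0.50 in N78-FUS-IDR. At the 68 that fell against FL 2, the medians against FL 1 were -1.38, -1.72, -0.76 and -0.63.

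**Figure D3:**
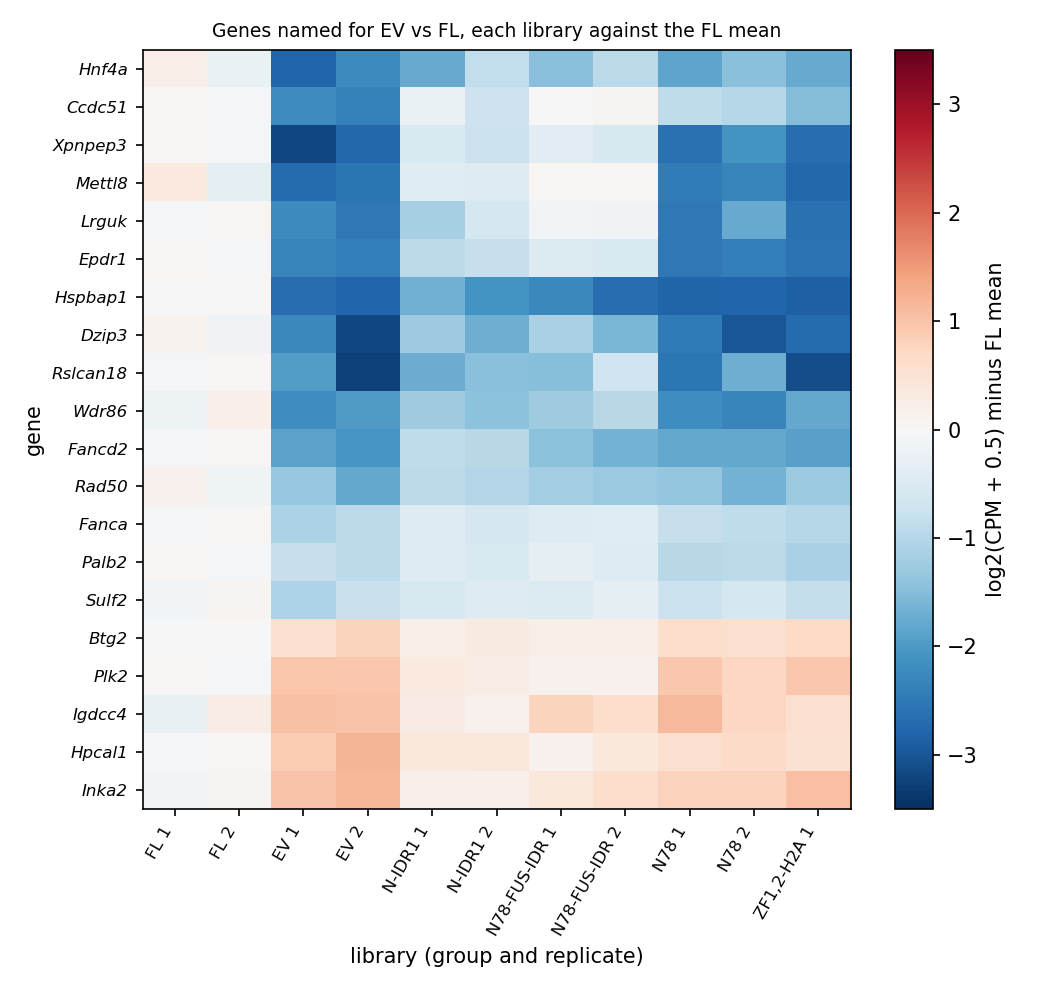
Level of the 20 genes named for EV against FL as largest changes, DNA repair genes or p53 targets in each of 11 libraries, as log2 of CPM plus 0.5 minus the FL mean (blue lower, red higher). Mettl8, for example, stood at 1.69 CPM in EV, 2.09 in N78 and 1.52 in ZF1,2-H2A, and at 9.48 in N-IDR1 and 13.8 in N78-FUS-IDR.

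Each mutant was also compared with EV, to see what it changes relative to no rescue. In N-IDR1, Xpnpep3 rose to 27.8 ± 2.9 from 5.19 ± 1.2 CPM (2.43, adjusted p = 0.018), Mettl8 rose by 2.49 (adjusted p = 0.032), and Zfp207 was the third and last gene. In N78-FUS-IDR, Mettl8 rose to 13.8 ± 0.05 from 1.69 ± 0.2 CPM (3.03, adjusted p = 0.0046), and Ttc8, a gene of the ciliary BBSome (3.51), Ccdc51 (3.21), Lrguk (2.68), Pcf11 (1.06) and Zscan4e (0.88) rose as well. Lefty2, an inhibitor of Nodal signalling, fell by 1.22, Sft2d3 by 1.21, Atp6v0a4 by 1.12, Neurod1 by 1.06 and Plk2 by 0.80 on the log2 scale. In N78 the 1 gene was Cttnbp2nl, lower by a log2 fold change of -2.33 (adjusted p = 0.002). In ZF1,2-H2A, Xkr6 fell to 7.61 from 41.1 ± 0.93 CPM (-2.43, adjusted p = 0.017) and Zfp207 rose. Gm53 (-1.73), A230103J11Rik and Gm17300, chosen after their values were seen, were lower too. A230103J11Rik and Gm17300 had 0 counts in the ZF1,2-H2A library and were at least 38.4-fold and 489-fold lower than in EV. These bounds rest on 1 library and cover counting error only, not the spread between libraries.

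The counts against EV were 3 for N-IDR1 (3 higher), 101 for N78-FUS-IDR (91 higher, 10 lower), 1 for N78 and 5 for ZF1,2-H2A (1 higher, 4 lower). At an unadjusted p under 0.05 they were 1849, 2223, 528 and 753. Those for N78 and ZF1,2-H2A lie under 0.05 of 21364 genes, so the share given by no true change may be smaller without the block. With the block they were 412 (290 higher), 1259 (690 higher), 3 and 7, and the 3 for N78 were Cttnbp2nl, Zfp207 (0.42) and Gm28036, the last chosen after its values were seen. For N-IDR1 the count was 1 without EV 1, 0 without EV 2 (edgeR, 1886 at an unadjusted p under 0.05) and 15 without N-IDR1 2. DESeq2 gave 164 with all libraries, and the block gave 121 without N-IDR1 1 and 215 without N-IDR1 2. For N78-FUS-IDR it was 14 without EV 1, 1 without EV 2, 5 without N78-FUS-IDR 1 and 4 without N78-FUS-IDR 2. For N78 it was 4 without EV 1 and 4 without N78 1, and for ZF1,2-H2A it was 2 without EV 2.

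The constructs that differ, as the labels name them, in the disordered part were compared with one another. Against N78, Cttnbp2nl rose in N-IDR1 (2.85, adjusted p = 0.00033) and in N78-FUS-IDR (2.72, adjusted p = 0.00048), and Mettl8 rose in both (2.18 and 2.72), as did Epdr1 (1.92 and 2.30). Pagr1a rose in N-IDR1 (4.45), with 41 and 240 counts in its libraries. In N78-FUS-IDR, Lrguk (2.31), Zscan4b (1.30), Zscan4e (1.14) and Zscan4c (0.99) rose too, while Dpys, an enzyme of pyrimidine breakdown, and Lefty2 fell by 1.28 and 1.25 on the log2 scale. Against N-IDR1, N78-FUS-IDR had higher Zscan4-ps3 (1.67), Zscan4b (1.59), Zscan4e (1.57), Zscan4a (1.51) and Zscan4c (1.39) and lower Zfp207 (-0.75). The 2-cell-like list was also higher in N78-FUS-IDR than in EV (median 0.71), N78 (0.82) and N-IDR1 (1.17). With an estimated correlation the p adjusted over 4 comparisons was 0.0043, 0.0029 and 0.00096, in tests added after the data were seen.

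The counts were 8 for N-IDR1 against N78 (7 higher, 1 lower), 34 for N78-FUS-IDR against N78 (32 higher, 2 lower) and 9 for N78-FUS-IDR against N-IDR1 (8 higher, 1 lower). With the block they were 221 (157 higher, 64 lower), 855 (468 higher, 387 lower) and 115 (72 higher, 43 lower), so the share of rises was smaller than without it. With the block and without N-IDR1 1 they were 49, 845 and 35, and without N-IDR1 2 the first was 104 and the last 86. For N-IDR1 against N78 the count was 3 without N-IDR1 1, 15 without N-IDR1 2, 3 without N78 1 and 2 without N78 2. For N78-FUS-IDR against N78 it was 1 without N78-FUS-IDR 1, 1 without N78-FUS-IDR 2, 4 without N78 1, 1 without N78 2 and 14 without N-IDR1 1, which belongs to neither group. For N78-FUS-IDR against N-IDR1 it was 4 without N-IDR1 1, 21 without N-IDR1 2, 2 without N78-FUS-IDR 1 and 0 without N78-FUS-IDR 2 (edgeR, 1184 at an unadjusted p under 0.05). With all libraries 51 passed by DESeq2.

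Gene span was examined because the study concerns splicing factors. In EV against FL, 1917 genes spanning over 100 kb had a median log2 fold change of -0.11, and 67 of them fell and 3 rose. The 3731 genes under 10 kb had a median of 0.08, with 29 falls and 10 rises, and between the limits 276 of 8844 fell and 18 rose. With the preset correlation the long genes were lower and the short genes higher (adjusted p = 0.0022 and 0.0028), which was lost with an estimated correlation (adjusted p = 0.18 and 0.36 with an estimated correlation). Without EV 2 the median of the short genes was -0.04, and the call was also lost for the short genes without FL 1 and for the long genes without EV 2. In N78 the medians were -0.17 for long and 0.18 for short genes (adjusted p = 1.6e-06 and 4.3e-08, adjusted p = 0.055 and 0.12 with an estimated correlation). With the block and an estimated correlation both passed (adjusted p = 0.019 each), a setting chosen after the data were seen. In N-IDR1, N78-FUS-IDR and ZF1,2-H2A the medians of long genes were -0.09, -0.09 and -0.13.

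The position of each construct library between FL (0) and EV (1) was measured along the EV minus FL direction of all tested genes, with direction and measurement taken from different libraries. N78 stood at 0.95 in both libraries and the 1 ZF1,2-H2A library at 1.13. N-IDR1 stood at 0.77 ± 0.11 (0.85 and 0.69) and N78-FUS-IDR at 0.48 in both libraries. Over the genes called in EV against FL the positions were 0.80 ± 0.02 for N78, 0.93 for ZF1,2-H2A, 0.44 ± 0.01 for N-IDR1 and 0.36 ± 0.01 for N78-FUS-IDR. These genes were called from all 4 FL and EV libraries. Selection therefore widens the EV minus FL difference and, through the FL libraries, each construct minus FL difference as well. It shifts these positions by an unknown amount, in a direction that was not tested. With genes of a mean CPM of 10 or more, a set chosen after the data were seen but not by the difference, N-IDR1 stood at 0.61 ± 0.03. There its shallow library N-IDR1 1 stood at 0.63 and N-IDR1 2 at 0.59. Over all tested genes with a prior count of 0.5 they stood at 1.01 and 0.75. The position of N-IDR1 thus depended on how genes with low counts were treated. The positions were not tested for differences between groups, and the 2 measurements share FL and EV libraries.

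**Figure D4:**
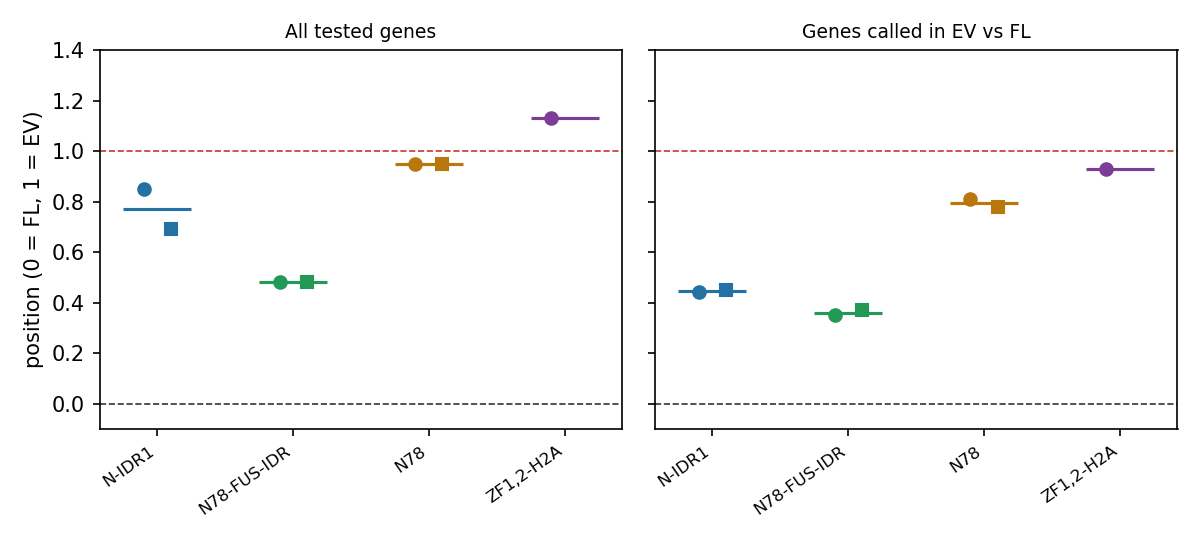
Position of each construct library between full-length rescue (0, dashed line) and empty vector (1, dashed line), with circles for replicate 1, squares for replicate 2 and lines for group means, over all tested genes and over the genes called in EV against FL. N78-FUS-IDR lay at 0.48 and 0.36 and N78 at 0.95 and 0.80 in the 2 panels.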

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

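The tests on the ZF1,2-H2A replicate 2 column were all chosen only after the result was seen.

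The column of ZF1,2-H2A replicate 2 was used in no comparison, yet it held signal: in 109 of 110 windows of 500 genes, its best match to ZF1,2-H2A replicate 1 at an offset of up to 60 places exceeded every window of the shuffled column (0.191 at most). The median of the best r was 0.471 over the windows, against 0.117 for the shuffled column, and neighbouring windows had offsets a median of 2 places apart, against 37 when shuffled, which is consistent with a shift of the row order within the column. A library of low complexity stays open, since its 21036 genes with a count were 0.974 times the lowest among 10 deeper columns thinned to its total (21594, in ZF1,2-H2A replicate 1). A right and a wrong label cannot be told apart, because at local offsets the column matched every group alike, with a median best r of 0.457 to 0.473 for the columns of other groups, and that for its own group -0.002 from the highest of these. Where in the handling of the table the shift arose stays open, no biological explanation was tested, and the column was not realigned, since that would assign values to genes by guesswork.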

How the results depend on the processing

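The choices of all 12 columns, of leaving out N-IDR1 1 or 2 with the block, of DESeq2 with the block, of the block with an estimated correlation, of split FL libraries and of the last 3 gene sets or pairings for positions were made only after the result was seen. Under RLE factors and a CPM above 1 in 2 libraries all 12 counts stayed within 1.5 times, and no named gene past its threshold changed direction under any setting except Acad10 with all 12 columns. The cause was not tested for any of the following, except where fewer samples or genes entered by construction and a count fell. Leaving out a library without the block can also leave the groups compared unequal in replicate number, which was not told apart from fewer samples. Comparisons are in the order EV, N-IDR1, N78-FUS-IDR, N78 and ZF1,2-H2A against FL, the same 4 mutants against EV, N-IDR1 against N78, N78-FUS-IDR against N78 and N78-FUS-IDR against N-IDR1, where a count not listed stayed within 1.5 times. By edgeR they were 459, 3, 12, 280, 139, 3, 101, 1, 5, 8, 34 and 9. DESeq2 gave 722, 121, 114, 654, 379, 164, 346, 4, 6 (within 1.5 times), 96, 233 and 51. No filter gave 875, 306, 245, 767, 599, 319, 529, 76, 113, 237, 347 and 230. The block gave 1910, 499, 296, 1951, 950, 412, 1259, 3, 7 (within 1.5 times), 221, 855 and 115. The block without N-IDR1 1 gave 1960, 83, 284, 1977, 934, 121, 1274, 2, 9, 49, 845 and 35, the block without N-IDR1 2 gave 202, 215, 104 and 86 for the 4 comparisons with N-IDR1, and DESeq2 with the block 1602, 577, 297, 1646, 871, 447, 1170, 37, 11, 312, 893 and 215. With only the 2 groups compared they were 189, 0, unmoved for N78-FUS-IDR, 460, 1281, 0, 3, 0, 31, 1, 11 and 0, where the 4 counts of 0 (edgeR) had 1382, 835, 339 and 790 genes at an unadjusted p under 0.05. With all 12 columns all were 0 (edgeR, 70 to 2081 genes at an unadjusted p under 0.05), and Acad10 in ZF1,2-H2A against FL was at 1.02. Library totals gave 5 for N-IDR1 against FL, 1 for N-IDR1 against N78 and 56 for N78-FUS-IDR against N78.

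Leaving out single libraries gave, in the same order, 54 to 176, 0 to 14, 1 to 5, 8 to 30, 14 to 22, 0 to 15, 1 to 14, 1 to 4, 2 to 5, 2 to 15, 1 to 4 and 0 to 21 genes, with fewer samples of the groups compared, which does not account for the counts that rose (without N-IDR1 2, and for N78 against EV without EV 1 or N78 1). Without N-IDR1 1, of another group, the counts were 474 for EV, 13 for N78-FUS-IDR, 275 for N78 and 147 for ZF1,2-H2A against FL and 71 for N78-FUS-IDR, 1 for N78 and 5 for ZF1,2-H2A against EV, and 14 for N78-FUS-IDR against N78.

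Lists past the threshold numbered 16 for EV, 16 for N-IDR1, 3 for N78-FUS-IDR, 16 for N78 and 13 for ZF1,2-H2A against FL. With an estimated correlation, with or without the block, they were 0, 0, 1, 0 and 0, and with the block N78-FUS-IDR had 8. Leaving out single libraries gave 8 to 16 for EV, 8 to 18 for N-IDR1, 3 to 7 for N78-FUS-IDR and 8 to 15 for ZF1,2-H2A.

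The median of genes under 10 kb in EV against FL (0.081) and over 100 kb (-0.111) no longer passed with an estimated correlation, nor with the block and one (0.077 and -0.114). Without single libraries the short genes ranged from -0.041 to 0.16 and the long genes from -0.146 to -0.079, with -0.102 no longer past the threshold without EV 2. For short genes library totals gave -0.017 for N-IDR1 and -0.006 for ZF1,2-H2A against FL. Without single libraries short genes ranged from -0.074 to 0.089 for N-IDR1, from -0.015 to 0.118 for N78-FUS-IDR and from 0 to 0.099 for ZF1,2-H2A against FL, the lowest values without N-IDR1 2, N78-FUS-IDR 2 and FL 1.

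Genes that fell in EV and in N-IDR1, N78-FUS-IDR, N78 and ZF1,2-H2A numbered 3, 9, 229 and 102, then 68, 66, 413 and 249 by DESeq2 and 236, 164, 873 and 550 with the block. With EV against FL 1 and the construct against FL 2, thus fewer samples, they were 0, 2, 18 and 14 (37, 33, 330 and 183 with the block), and the other way round 0, 1, 24 and 9 (27, 39, 303 and 270 with the block). The 2 counts of 0 (edgeR) had 328 and 339 shared falls at an unadjusted p under 0.05.

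Positions moved by more than the SD between replicates, which was near 0 for N78-FUS-IDR and N78. Over called genes they were 0.44 (N-IDR1), 0.36 (N78-FUS-IDR), 0.80 (N78) and 0.93 (ZF1,2-H2A), and against the same number 0.44, 0.36, 0.79 and 0.95. Not cross-fitted they were 0.58, 0.44, 0.66 and 0.75. For N78-FUS-IDR and N78 they were 0.46 and 0.94 with library totals, 0.50 and 0.96 with a prior count of 0.5, and 0.45 and 0.93 with a CPM above 1. They were 0.45 and 0.88 with the direction from replicate 1, 0.50 and 1.02 from replicate 2, and 0.45 and 0.92 against the same number over all genes. With a mean CPM of 10 or more N-IDR1, N78-FUS-IDR and N78 stood at 0.61, 0.41 and 0.97.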

Other observations

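The tests of scaling, low counts and depth were planned before their results were seen. The tests of Zscan4 copies and of single libraries, those of low counts among the blocked calls, the splits by fold, and the comparison of replicate numbers were chosen only after the result was seen.

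Newly made RNA also differed between the replicate numbers, across the 5 groups with both libraries. The blocked fit takes this difference as equal in all groups, which was not tested. In the blocked fit 3985 genes differed, 1715 higher and 2270 lower in replicate 2, of which 86 differed over 2-fold. Replication-dependent and other histone genes were higher in replicate 2 for 43 of 63 members, with 0 lower (median log2 difference 0.38, adjusted p = 9.1e-38, adjusted p = 0.27 with an estimated correlation). H3c8 differed by 0.68 and H3c15 by 0.72, the latter higher in replicate 2 in each of the 5 groups with both libraries, as with 119.8 and 175.6 CPM in FL. Immediate early genes had 13 of 30 higher and 1 lower (adjusted p = 1.4e-08, adjusted p = 0.27 with an estimated correlation), and 11 of 26 DNA repair genes were lower with 0 higher (adjusted p = 7.1e-06, adjusted p = 0.53 with an estimated correlation). The mitochondrial ribosomal RNA mt-Rnr2 had a log2 difference of -1.19 and Snhg14, a noncoding transcript of the Ube3a region, of -1.32.

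More genes fell than rose in EV against FL, 92.4% of 459. Under RLE factors and library totals at least 91.8% of calls were lower, so the choice among these scalings does not account for the excess. They shifted the median log2 fold change of all genes only from 0.003 to 0.013 and -0.056, too little to test a larger error of scaling. Without the block, counting noise at low levels as the whole cause is argued against by calls with a mean CPM of 10 or more. Of these 300 genes 89.0% were lower. Thinning the 4 libraries to one total left 91.8% of 425 calls lower, which argues against the difference in depth. With the block 64.6% of 1910 calls were lower (54.6% of the 1453 under 2-fold) and 56.9% of the 1477 with a mean CPM of 10 or more, so low counts may account for part of that excess, but are argued against for calls of 2-fold or more (96.3% of 457) by 96.4% of the 139 with such a CPM. The loss of ZFP207 stays open and was not tested apart from a difference between the cells that carry the constructs, as does a global change of RNA output, because no spike-in is described. An effect of the full-length construct beyond the natural level was not told apart either, since every group received IAA.

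The 2-cell-like list was higher in N78-FUS-IDR than in every other group with 2 libraries. Reads shared between the Zscan4 copies as the whole cause are argued against by a median log2 fold change of 0.92 against FL in the 22 members outside that family. Those members include other near copies, such as the Usp17l family, so reads shared within these stay open. Some had low counts, such as Tdpoz4 with 1.04 and 0.37 CPM in FL. Both members called over all genes were Zscan4 genes. With the block Gm4340, Gm5662, Gm2016 and Usp17lc rose outside that family. A single library as the cause is argued against by the smaller of the 2 same-number differences in median log2 CPM from FL, 0.55, the other being 1.10. The difference in construct stays open and untested, as does a difference between the cells that carry the constructs, since the labels do not say whether a construct was carried by several lines.

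Cttnbp2nl stood out in N78, though an effect of the construct cannot be told apart from a difference between the cells. It stood at 9.65 ± 2.2 CPM there and at 46.4 to 70.5 in the other 5 groups, and it was called in N78 against FL, EV, N-IDR1 and N78-FUS-IDR whichever library of the compared groups was left out.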
